A study of Homo sapiens with 4 samples.

How the data were processed

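Messenger RNA was measured by sequencing in 4 libraries of human trophoblast stem-like cells (TSLCs), cells with the growth properties of placental stem cells that had been derived from embryonic stem cells. The libraries came from 2 passage numbers, passage 10 and passage 15, with 2 biological replicates each. Per the labels' protocols, the cells were grown in trophoblast stem cell medium holding EGF, the GSK3 inhibitor CHIR99021, inhibitors of TGF-beta receptor signalling, valproic acid and the ROCK inhibitor Y27632, total RNA was purified on RNeasy columns, and poly(A)-selecting TruSeq mRNA libraries were made from it.

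The authors deposited a single table of TPM values, a length-corrected relative abundance of transcripts, with 58825 rows and a column per library. Per the submitters' processing notes, the tools included STAR 2.6.1d and RSEM 1.3.3, and the genome build was GRCh38. The gene annotation, the read depth and whether counting used strand are not given in the sources used here. TPM divides each gene's estimated reads by its length and scales every library to the same total, so the values keep no depth, and the sequencing depth of each library is unknown. No counting interval could therefore be given, and precision was taken from the spread between replicates. A rise of abundant transcripts lowers the TPM of all others in that library. Reads from near-identical genes (the chorionic gonadotropin beta genes, the pregnancy-specific glycoproteins, the galectins LGALS13 and LGALS16, pseudogenes) were divided between them by estimation, so single members of such families are uncertain, as are genes antisense to another gene.

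Row symbols were matched to GENCODE release 29 on GRCh38 for gene type and coordinates. Of the rows, 98.7% had a symbol in that annotation, and 99.2% of those with a mean of at least 1 TPM. A date stood in place of a symbol in 27 rows, and 25861 rows were at 0 in all 4 libraries. XIST, TSIX and genes on chromosome Y were left out of every step.

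The passages were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend) on log2(TPM + 1), over the 15018 rows with a mean of at least 1 TPM, with a two-sided moderated test and Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(TPM + 1) scale, with a pseudocount of 1, which understates changes of low genes. The residual degrees of freedom were 2 and the prior degrees of freedom 6.31. The replicates are called biological in the design text, but nothing says that they were separate derivations, so p-values measure only the spread between these samples.

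Gene lists were fixed before the data were examined: 13 lists of cell states, 16 of processes and 4 of RNA quality, with 712 distinct genes, of which 708 were found (20 under an older symbol). TGFB1, ALPPL2, H3C2 and H3C3 were not analysed here. The 31 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01 between genes, again with Benjamini-Hochberg adjustment, and also with camera at an estimated correlation and with fry. The level of each list was described by the median TPM of its members in each library and by the percentile of that median among 10000 random lists of the same size. The random lists were drawn from all 32459 rows with a mean above 0, of which 15018 had a mean of at least 1 TPM. A list of expressed genes of any kind therefore ranks high.

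The genes named were chosen by a rule fixed before the data were examined: up to 12 genes per direction with the largest change among those past the threshold and without overlap between the passages, per list up to 5 members with the highest level and up to 3 with the smallest p, the 15 most abundant genes that are neither ribosomal protein nor mitochondrial genes, and the trophoblast, pluripotency and amnion members on which a count of expressed members rests. Clone names were passed over. A gene named outside this rule is said to have been chosen after its values were seen.

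The test was checked on 10 simulated tables of 15018 genes for the comparison of passage 15 with passage 10, with 200 changed genes each. It recovered 43.7% of genes changed by 1 on the log2 scale and 98.8% of those changed by 2, and 5.19% of its calls were false. Of simulated lists without a shift, 1% had p under 0.05. The changed genes and the list genes were drawn from genes at about 5 TPM or more, so recovery among lower genes was not measured. The simulated genes varied independently, with spreads drawn from the prior fitted to these data. In the real libraries the estimated correlation between list genes was 0.67 for syncytiotrophoblast, 0.72 for mitochondrial and 0.91 for G2/M genes. The simulated false rates therefore need not hold for lists whose genes vary together.

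The alternatives tried were other pseudocounts, other filters on low values, TMM and quantile scaling, rescaling without mitochondrial and ribosomal protein genes, a replicate block, no intensity trend, robust variance estimation, a minimum fold change, summed rows of the same symbol, and leaving out each library in turn. Protein-coding rows alone were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.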

Results

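The series measured the transcriptome of human embryonic stem cell-derived TSLCs at passage 10 and passage 15, in 2 replicate libraries each, to assess the state of the cells. Each library held between 14890 and 15071 genes at 1 TPM or more. The mitochondrial genome supplied 5.36% and 6.43% of all TPM in the passage 10 libraries and 7.76% and 9.35% in the passage 15 libraries. Ribosomal protein genes supplied 14.975% ± 0.516 (SD, n = 2) at passage 10 and 14.7% ± 0.172 (SD, n = 2) at passage 15.

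The first question was which cell state the libraries showed. Genes of trophoblast stem cells and of the cytotrophoblast, the proliferating layer of the placental villus, were expressed throughout: all 33 members of that list had a mean of at least 1 TPM over the 4 libraries, and 20 had at least 100 TPM. This list lay above every one of 10000 random lists of the same size, but so did the housekeeping, S-phase and cholesterol synthesis lists. That rank is therefore not particular to trophoblast. The median level of the trophoblast stem cell list was 140 ± 18.5 TPM (SD, n = 4). The simple-epithelium keratins KRT8 (3417 ± 472 TPM, SD, n = 4), KRT18 (2984 ± 499) and KRT19 (1042 ± 48.6) and the retrotransposon-derived imprinted gene PEG10 (2669 ± 831) were among its most abundant members. The transcription factors GATA3 (316 ± 64.2 TPM, SD, n = 4), GATA2 (278 ± 41.3), TFAP2A (111 ± 26.7), TFAP2C (76.5 ± 12.7) and TEAD4 (65.9 ± 10.039) were also expressed. ELF5 and TP63, a regulator of trophoblast self-renewal and a factor of the cytotrophoblast, were lower, at 4.97 ± 1.07 and 11.9 ± 1.57 TPM (SD, n = 4).

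Differentiated trophoblast genes were present beside them. Of 34 syncytiotrophoblast genes, which mark the fused hormone-producing layer of the placenta, 31 had at least 1 TPM, and the median level of the list was 62.6 ± 32.6 TPM (SD, n = 4). CGA, the alpha subunit of chorionic gonadotropin, ranked number 2 at passage 10 and number 16 at passage 15 among all genes that are neither ribosomal protein nor mitochondrial, by its mean level in each passage. Of the 17 trophectoderm genes, 15 reached 1 TPM. CDX2, a factor of the early trophectoderm, had 0.25 ± 0.122 TPM (SD, n = 4). Extravillous trophoblast, the invasive lineage, was represented by 15 of 22 genes, with a list median of 3.22 ± 0.331 TPM (SD, n = 4) at percentile 90.5 of random lists. HLA-G, an HLA class I gene of that lineage, reached 450 ± 128 TPM (SD, n = 4). HLA-A (386 ± 15.9 TPM) and B2M (1772 ± 262) are in the HLA class I list but not in the extravillous list, and do not mark that lineage. Reads of HLA genes are shared between related genes, which leaves their single values uncertain.

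Core pluripotency factors were near or at 0. POU5F1 had 0.238 ± 0.135 TPM and NANOG 0.0425 ± 0.0785 (SD, n = 4), and SOX2 and TDGF1 were listed at 0 in all 4 libraries. Another part of the pluripotency list was expressed: CD24 (514 ± 35.9 TPM, SD, n = 4), LIN28A (58.7 ± 10.1), L1TD1 (49.5 ± 6.17), ZFP42 (45.3 ± 5.91), DPPA4 (44.1 ± 5.27) and DNMT3B (43.3 ± 1.19). The median of the pluripotency list was 0.345 ± 0.215 TPM (SD, n = 4), at percentile 14.6 of random lists. In all, 12 of its 25 genes reached 1 TPM. Of 18 naive pluripotency genes, 5 did so, among them KLF5 (58.1 ± 1.63 TPM, SD, n = 4) and TFCP2L1 (53.5 ± 15.9), both also transcribed in trophoblast.

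The lists of other lineages had medians below those of the trophoblast stem cell, trophectoderm and syncytiotrophoblast lists. They were 0.878 ± 0.360 TPM (SD, n = 4) for amnion, with 10 of 20 genes at 1 TPM or more, 2.03 ± 0.211 for surface ectoderm and keratinocytes, 1.11 ± 0.176 for mesenchyme, 0.176 ± 0.101 for endoderm, 0.0413 ± 0.0371 for endothelium and blood, 0.0275 ± 0.0343 for primitive streak and mesoderm, and 0.005 ± 0.00408 for neural ectoderm. Against random lists of the same size, most of whose rows were under 1 TPM, the surface ectoderm (percentile 73.7), mesenchyme (67.0) and amnion (51.4) lists were not low. The endoderm list lay at percentile 8.02, the endothelial and blood list at 0.07, and the mesoderm and neural lists at 0. The amnion factors ISL1 and TFAP2B had 0.0875 ± 0.055 TPM (SD, n = 4) and a listed value of 0 in all libraries, while VTCN1 had 12.6 ± 1.37 TPM. Single genes of these lists were abundant, such as the collagen gene COL1A2 (1029 ± 194 TPM, SD, n = 4). The samples hold no reference cell type, so these levels describe the 4 libraries alone.

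**Figure D1:**
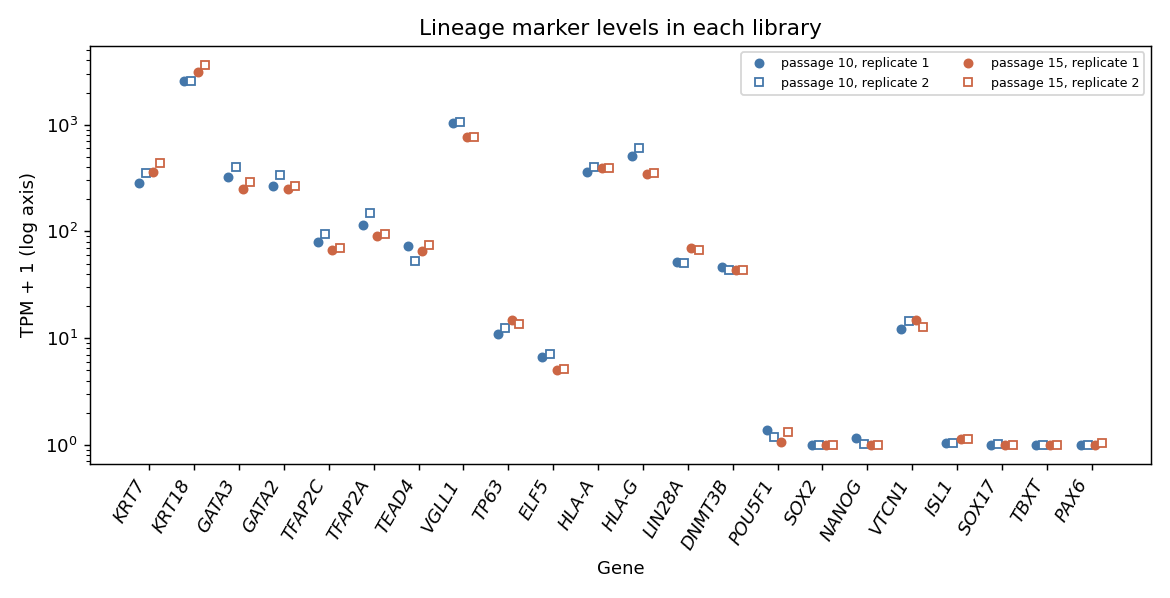
TPM + 1 on a log axis for 22 marker genes, with a point for each library, coloured by passage and shaped by replicate. KRT18 has a mean of 2984 TPM and GATA3 of 316 TPM, whereas SOX2 and TBXT sit at the bottom of the axis in every library.

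The markers in that plot were chosen from the lists after their values were seen.

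The comparison of passage 15 with passage 10 asked what changed with further culture. Of 31 tested syncytiotrophoblast genes, 14 fell, 1 rose and 16 did not pass, and the list was lower by camera with the preset correlation (adjusted p = 8e-15) but not with an estimated one (adjusted p = 0.686 with an estimated correlation). CGA went from 7208 ± 2197 TPM (SD, n = 2) at passage 10 to 2211 ± 55.1 at passage 15, a log2 fold change of -1.67 ± 0.19 (SE; limma, Benjamini-Hochberg adjusted p = 0.0157). CYP19A1, the aromatase that makes oestrogens, changed by -1.53 ± 0.19 (SE; adjusted p = 0.0193), from 556 ± 137 to 189 ± 13.4 TPM. Genes of other kinds rose, among them the cancer-testis gene XAGE3 (12.045 ± 0.940 to 85.5 ± 1.51 TPM, SD, n = 2; log2 fold change 2.73 ± 0.17, adjusted p = 0.00126), the transcription factor genes HAND1 and GATA4, and the imprinted long noncoding RNA MEG3. Markers of trophoblast stem cells did not pass the test.

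In total, 204 of 15018 genes passed the threshold, 91 higher and 113 lower at passage 15 (44.6% higher), and 2567 had an unadjusted p under 0.05. With TMM scaling the count was 83, of which 57.8% were higher, and with quantile normalization it was 75, of which 58.7% were higher. Of the 204, 147 were protein-coding, 61 higher and 86 lower. The count was 1441 without passage 10 replicate 1, 42 without passage 10 replicate 2, 3 without passage 15 replicate 1 and 2 without passage 15 replicate 2. Across genes, the SD of log2 differences was 0.41 between the passage 10 replicates and 0.36 between the passage 15 replicates. Passage 10 replicate 1 differed from passage 15 replicates 1 and 2 by 0.41 and 0.46, and passage 10 replicate 2 by 0.54 and 0.57, so that 1 of the 4 pairs across passages was as close as the passage 10 replicates.

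With p-values adjusted over the syncytiotrophoblast list alone, 23 of its 31 tested genes fell and 1 rose. The median log2 fold change of the list was -1.09. Besides CGA and CYP19A1, the genes that fell included the chorionic gonadotropin beta genes CGB3, CGB5 and CGB8 (log2 fold changes -1.36, -1.33 and -1.31), the placental galectin genes LGALS13 and LGALS16 (-1.52 and -1.49), CYP11A1 (-1.20), which starts steroid synthesis, the relaxin-family gene INSL4 (-1.43) and the envelope gene ERVV-1 (-1.34). The naming rule allowed fewer genes per list, so some of the falling genes named here were chosen after their values were seen. Reads of the gonadotropin beta genes and of the galectins are shared between near-identical copies. Together, the CGA and CGB rows made up 1.25% ± 0.379 (SD, n = 2) of all TPM at passage 10 and 0.425% ± 0.0204 at passage 15. The exception was TFPI2, a serine protease inhibitor gene, which rose from 25.7 ± 8.29 to 93.2 ± 9.75 TPM (SD, n = 2; log2 fold change 1.85 ± 0.23, adjusted p = 0.0193). Between the passage 10 libraries, 29 of the 31 genes were higher in replicate 2, by a median of 0.51 on the log2 scale. The number of list genes that fell was 3 without passage 10 replicate 2, 23 without passage 10 replicate 1, and 0 without either passage 15 library. The list median was -0.85 and -1.35 without passage 10 replicates 2 and 1, and -1.16 and -1.09 without passage 15 replicates 1 and 2.

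**Figure D2:**
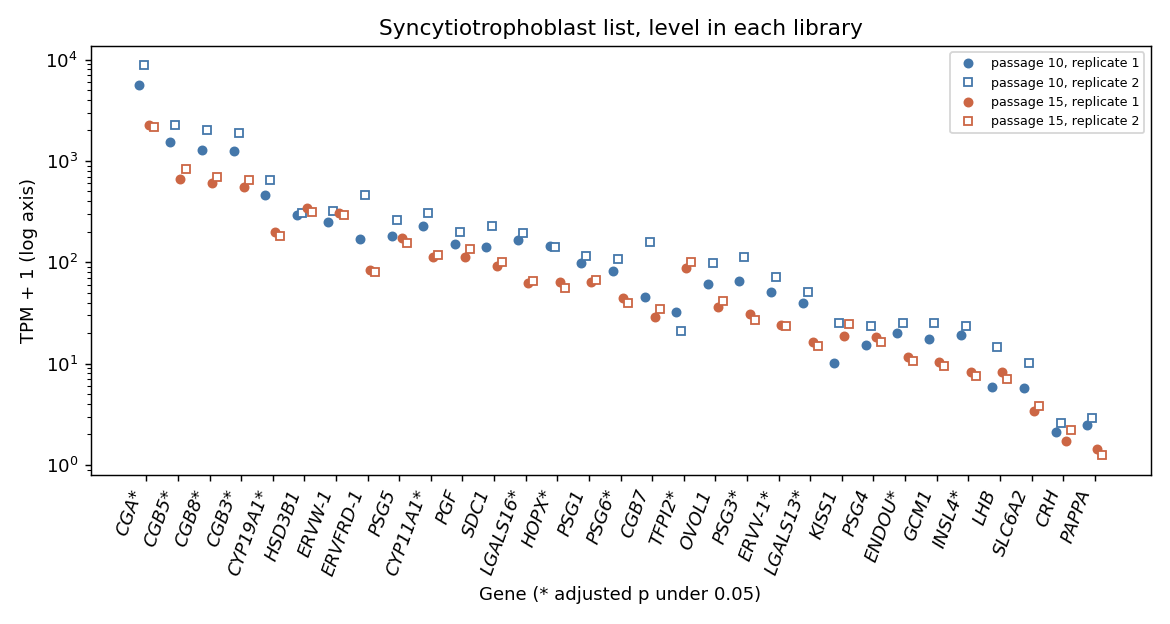
TPM + 1 on a log axis for the 31 tested syncytiotrophoblast genes, ordered by mean level, with a point for each library, coloured by passage and shaped by replicate, and an asterisk at genes with an adjusted p under 0.05. CGA lies between 5654 and 8761 TPM at passage 10 and between 2172 and 2250 TPM at passage 15, and TFPI2 is higher at passage 15.

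None of the 33 trophoblast stem cell and cytotrophoblast genes passed the test over all genes, and with p-values adjusted over the list alone 1 rose and 3 fell. The median log2 fold change of this list was -0.10 (camera adjusted p = 0.79). The epidermal growth factor receptor gene EGFR had the smallest p of the list, with 230 ± 39.6 TPM at passage 10 and 131 ± 0.325 at passage 15 (SD, n = 2; limma adjusted p = 0.0664). In the extravillous list, ITGA1, the integrin alpha 1 gene, fell (log2 fold change -1.89 ± 0.24, SE, adjusted p = 0.0193) and the other 14 tested genes did not pass. In the trophectoderm list, HAND1 rose and the other 14 did not pass. Camera called neither list (adjusted p = 0.292 and 0.441). The extravillous result rested on the passage 10 libraries: the list was called lower without passage 10 replicate 1 (median log2 fold change -0.63, adjusted p = 0.0156) and had a positive median of 0.12 without passage 10 replicate 2 (adjusted p = 0.465).

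HAND1, a factor of trophoblast, amnion and mesoderm, went from 3.75 ± 1.90 to 19.2 ± 0.841 TPM (SD, n = 2; log2 fold change 2.15 ± 0.28, limma adjusted p = 0.0193), and GATA4, a factor of endoderm and heart, from 0.575 ± 0.0354 to 5.55 ± 0.0141 TPM (2.06 ± 0.22, adjusted p = 0.011). Other genes that rose were GTSF1, a germline gene of the transposon-silencing pathway (2.05), the neuronal cytoskeleton genes STMN2 (1.85) and NEFL (1.78), RCN3 (1.84) and MEG3 (1.81). Among the named genes that are neither pseudogenes nor small RNAs, the largest decreases were those of TREML2 (-2.28), PLAC4 (-1.91), ITGA1 and TREM1 (-1.78), where TREML2 and TREM1 are neighbouring receptor genes on chromosome 6 and PLAC4 lies antisense to another gene. Short RNAs and pseudogenes filled the rest of the named places. RNU6-914P and RF02110 were listed at 0 in both passage 10 libraries and RF01210 and RF00019 in both passage 15 libraries, and TSSC2, FDX1P1, SEC22B2, RNA5SP244, SNORA31 and RF02192 also passed. A poly(A)-selected library measures such RNAs poorly.

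Several other lists were called by camera with the preset correlation, and none of the 11 called lists was called with an estimated correlation or by fry. For these lists, here and in the paragraphs that follow, p with an estimated correlation is camera's unadjusted p. Adjusted, it was 0.838 for the G2/M and S-phase lists and 0.686 for the other called lists. All 13 mitochondrial genome transcripts were higher at passage 15, with a median log2 fold change of 0.62 (camera adjusted p = 8.68e-11, and p = 0.143 with an estimated correlation). None of them passed over all genes, and all 13 passed when adjusted over the list alone. All 30 genes of the G2/M phase had a positive sign (median 0.45, adjusted p = 1.97e-07, and p = 0.346 with an estimated correlation), and none passed over all genes or adjusted over the list alone. UBE2C, a mitotic ubiquitin-conjugating enzyme, had 98.9 and 56.5 TPM in the passage 10 libraries and 130 and 126 TPM in the passage 15 libraries. Without passage 10 replicate 2, the G2/M median was 0.04 and the adjusted p was 0.0602, and without passage 10 replicate 1 the median was 0.87. S-phase genes had a median of 0.20 (24 of 30 positive, adjusted p = 0.0082, and p = 0.513 with an estimated correlation), with none past the threshold and 1 lower adjusted over the list alone. Without passage 10 replicate 2 the S-phase median was -0.03 (adjusted p = 0.769), and without passage 10 replicate 1 it was 0.48.

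Of 21 interferon response genes, 19 had a negative sign, with a median of -0.53 (camera adjusted p = 5.78e-05, and p = 0.195 with an estimated correlation). None passed over all genes, and 5 fell when adjusted over the list alone. The interferon median was -0.32 with a pseudocount of 5, -0.27 at a mean of at least 5 TPM and -0.29 without a filter. Its size thus rested partly on low genes, while camera with the preset correlation still called the list in each setting. MX1, an antiviral GTPase, had 21.3 and 35.8 TPM at passage 10 and 12.7 and 9.05 TPM at passage 15. Without passage 10 replicate 2, the interferon median was -0.29 and the adjusted p was 0.0484. Of 5 tested cancer-testis genes, XAGE3 and MAGEB2 (log2 fold change 1.33) rose, and 3 rose when adjusted over the list alone (list adjusted p = 0.00122, and p = 0.0628 with an estimated correlation). In the matrix and integrin list, COL18A1 (1.61) and LAMA3 (1.32) rose, ITGA1 fell and 26 genes did not pass, while 6 rose and 2 fell adjusted over the list alone (list adjusted p = 0.0122, and p = 0.0809 with an estimated correlation).

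In the mesenchyme list, ACTA2 (1.36) and COL5A1 (1.12) rose and 9 genes did not pass, with 5 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0185, and p = 0.199 with an estimated correlation). In the amnion list, HAND1 and the claudin gene CLDN10 (1.13) rose, also when adjusted over the list alone, and 8 did not pass (adjusted p = 0.0104, and p = 0.0901 with an estimated correlation). Among WNT targets, CDX1 (1.24) rose and 11 did not pass, with 2 higher adjusted over the list alone (adjusted p = 0.0187, and p = 0.162 with an estimated correlation). Of 10 surface ectoderm and keratinocyte genes, none passed and 4 rose adjusted over the list alone (adjusted p = 0.00378, and p = 0.0734 with an estimated correlation). With all libraries, the list medians were 0.18 for amnion, 0.33 for matrix, 0.45 for mesenchyme, 0.28 for surface ectoderm and 0.19 for WNT targets. Leaving out passage 10 replicate 1 ended the calls of the amnion (median 0.33, adjusted p = 0.131), matrix (0.12, adjusted p = 0.369), mesenchyme (0.32, adjusted p = 0.256) and surface ectoderm (0.27, adjusted p = 0.123) lists. Leaving out passage 15 replicate 1 ended that of the amnion list (median 0.24, adjusted p = 0.0702) and leaving out passage 15 replicate 2 that of the WNT list (median 0.17, adjusted p = 0.11). Medians of lists that stayed called moved by over 1.5 times for amnion without passage 10 replicate 2 (0.28), for WNT targets without passage 10 replicate 1 (0.37), and for the matrix list without passage 10 replicate 2 (0.19) and without passage 15 replicate 2 (0.15). Without a filter on low values, the mesenchyme (median 0.11, adjusted p = 0.142) and WNT (0.08, adjusted p = 0.0667) lists were not called. The amnion, matrix, surface ectoderm and cancer-testis lists stayed called without it, with smaller medians of 0.09, 0.17, 0.1 and 0.06. The cancer-testis median with the filter was 0.98.

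**Figure D3:**
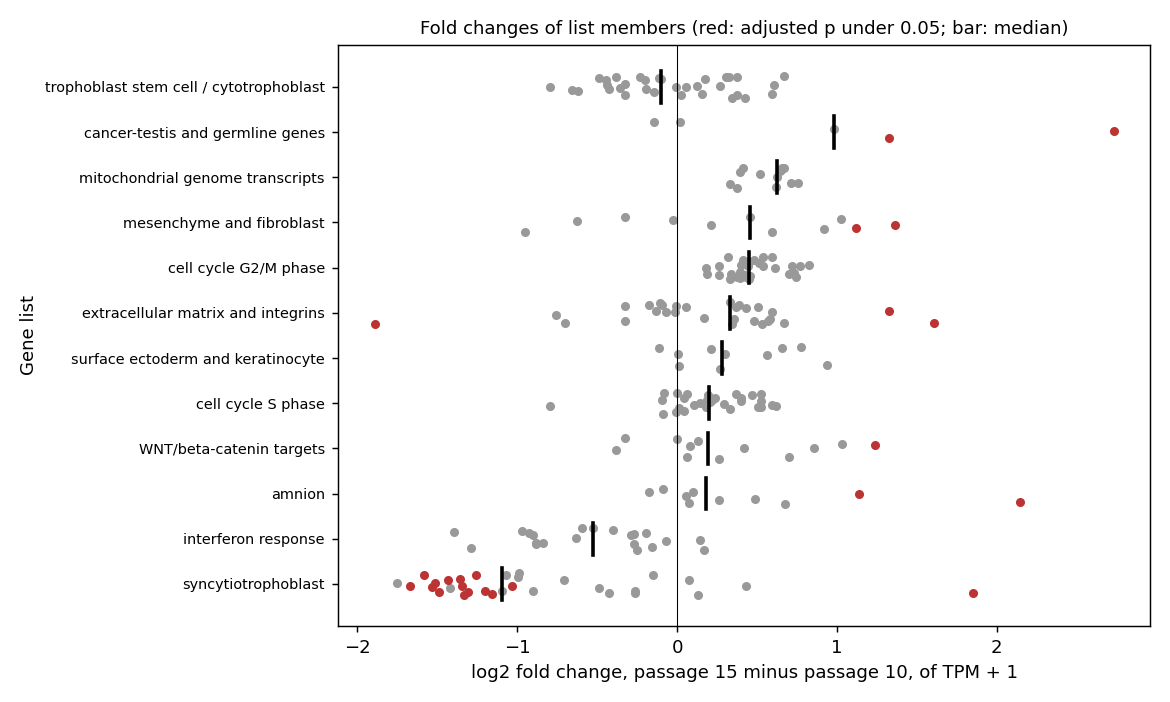
Log2 fold change of TPM + 1, passage 15 minus passage 10, of each tested member of the 11 lists called by camera and of the trophoblast stem cell list, with a bar at each list's median and red points for genes with an adjusted p under 0.05. The syncytiotrophoblast median lies at -1.09 and the mitochondrial one at 0.62, and the trophoblast stem cell list is centred at -0.10.

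The other lists were not called. Among imprinted genes, MEG3 rose and the growth factor gene IGF2 fell (log2 fold change -1.01 ± 0.14, SE, limma adjusted p = 0.0206; 880 ± 36.1 to 435 ± 15.4 TPM, SD, n = 2), and the list gave adjusted p = 0.566. In the pluripotency list, PODXL, a sialomucin gene also expressed in epithelia, rose (1.50, list adjusted p = 0.601). ZFP57, a zinc finger gene that guards imprints, rose in the DNA methylation list (1.57, list adjusted p = 0.566), GATA4 in the endoderm list (list adjusted p = 0.566) and IGFBP7 in the p53 and senescence list (1.36, list adjusted p = 0.601). CDH5 fell in the endothelial list (-0.92, list adjusted p = 0.566) and ID2 among TGF-beta and BMP targets (-0.97, list adjusted p = 0.689). No gene passed in the cholesterol (camera adjusted p = 0.225), histone (0.287), hypoxia and glycolysis (0.292), stress response (0.391), EGF and MAPK (0.463), housekeeping (0.601), naive pluripotency (0.601), HLA class I (0.601), ribosomal protein (0.601) and epithelial junction (0.836) lists. Leaving out a passage 10 library gave calls in 4 of these. Without replicate 1, the cholesterol (adjusted p = 6.75e-08) and stress response (0.00946) lists were lower, and without replicate 2 the cholesterol (0.00244), hypoxia and glycolysis (0.00916) and EGF and MAPK (0.0405) lists were higher. The median was negative while camera gave a positive direction for the pluripotency (-0.07), p53 (-0.06) and epithelial junction (-0.07) lists. The mesoderm and neural lists had fewer than 5 tested genes and were not tested as lists.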

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

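The test on protein-coding genes alone was chosen after the data were seen. All 204 genes called between the passages kept their direction under the scaling, pseudocount and trend alternatives, and those present in the others kept theirs too. This is no independent support, since none of the 204 overlapped between the passages. Another pseudocount, another trend or a left-out library could therefore not change their direction. The number called was 204, and it moved to 0 without a filter (3508 genes at an unadjusted p under 0.05 by limma), 83 with TMM scaling, 75 with quantile normalization, 94 without an intensity trend, 348 with robust variances and 479 among protein-coding genes, where fewer genes were tested. It ranged from 2 to 1441 when a library was left out, which leaves a single library in its passage, assumed to vary like the others. No shared replicate effect was visible (r = 0.034 across genes between the replicate differences of the passages). This cannot show whether replicates of the same number were carried on from the same culture. The replicate block gave 141 genes, 125 of them among the 204, and changed no list call. Of the named genes, 10 lost their call with the replicate block, 14 with TMM scaling and 43 without a filter.

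Of 11 lists called, 0 were called with an estimated correlation and 0 by fry. With an estimated correlation the adjusted p was 0.686 for the syncytiotrophoblast list, 0.686 for mitochondrial transcripts and 0.838 for G2/M genes, and by fry 0.282, 0.282 and 0.602. The estimate rests on 2 residual degrees of freedom. When a library was left out, the G2/M adjusted p ranged from 4.04e-16 to 0.0602, the latter without passage 10 replicate 2. The cholesterol synthesis list, not called, turned to higher without passage 10 replicate 2 (adjusted p = 0.00244, median 0.12), and the cause was not tested; its adjusted p ranged from 6.75e-08, lower, without passage 10 replicate 1 to 0.348 without passage 15 replicate 1. The median of the trophoblast stem cell list went from 140 to 180.0 TPM when rescaled without mitochondrial and ribosomal protein genes, since each remaining gene then takes a larger share. Depth is unknown, so what it limits could not be tested.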

Other observations

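The tests on the syncytiotrophoblast genes, the G2/M genes, GATA4 and HAND1, and the blocks of chromosome 11 were chosen after the results were seen, as was the HOX gene set. The autosome, GC content and retinoic acid tests were set before their results were seen, except that the demand that the autosome bound be cleared by more than the standard error was applied after its value was seen.

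HOX genes, which pattern the body axis, were low but mostly higher at passage 15. Of 9 with a mean of at least 1 TPM, 8 had a positive sign, with a median log2 fold change of 0.68 (limma's camera, adjusted p = 4.88e-06 over the added lists, and adjusted p = 0.0784 with an estimated correlation, for a set picked from these data). HOXC10 (1.07 ± 0.474 to 5.63 ± 0.721 TPM, SD, n = 2; limma adjusted p = 0.0252) and HOXA1 (1.53 ± 0.516 to 4.94 ± 0.290 TPM, adjusted p = 0.0499) rose. The median stayed between 0.44 and 0.89 when any library was left out. One hypothesis was a retinoic acid response, which would raise other retinoic acid targets too. Of 15 such targets listed, 8 were tested. Of these, 3 had a positive sign (TGM2, CYP26B1 and DHRS3), and none passed the threshold. As a list the tested targets did not rise by limma's camera (adjusted p = 0.983 over the added lists), which argues against a shared rise of these 8 genes. A retinoic acid response that raises only some targets stays open.

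The passage 10 replicates differed in cell cycle and lipid genes. All 30 G2/M genes were lower in replicate 2 than in replicate 1, by a median of -0.86 on the log2 scale, and 21 of 23 cholesterol synthesis genes were higher, by a median of 0.71. Without passage 10 replicate 2, the G2/M median difference between passages was 0.0367, so that library alone may account for the higher G2/M genes at passage 15. Whether its culture differed in density or in its share of dividing cells was not tested, and an effect of passage stays open.

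The lower syncytiotrophoblast genes at passage 15 were weighed in the same way. A shift of the TPM total by the higher mitochondrial share at passage 15 is not the cause, since after rescaling without mitochondrial and ribosomal protein genes the list median was -1.1 (SD over genes 0.77). A single passage 10 library is not the whole cause either, since the median was -0.848 (SD over genes 0.73) without passage 10 replicate 2, although 3 members in place of 14 then passed. A smaller share of syncytiotrophoblast-like cells may account for it: the 14 members that fell did so by similar amounts, with an SD of 0.177 against a median standard error of 0.194. TFPI2 rose, however, and genes picked for falling tend to have similar values, so a smaller share of such cells and lower expression per cell cannot be told apart. An effect of passage itself stays open.

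Genes of chromosome 11 were shifted upwards as a whole at passage 15. A test for a gained or lost autosome had set bounds of 0.3 for and 0.2 against it, and chromosome 11 had the largest distance of the 22 autosomes from the median of all autosomal genes, 0.198 with a bootstrap SE over genes of 0.0135, inside the lower bound by less than that SE. Read against the bound alone, as first done, this value counts against a gained or lost autosome; with the SE, the test did not decide. The next largest distance was 0.0781. Both passage 15 libraries (0.0747 and 0.119) lay above both passage 10 libraries (-0.0961 and -0.0883), although other autosomes reached -0.108 and 0.114 in single libraries, and the distance was between 0.165 and 0.229 when any library was left out. A trend with GC content or transcript length is not the whole cause, since the distance was 0.175 ± 0.0162 (SE) after that trend was removed, with no other autosome beyond 0.0398.

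An extra copy of chromosome 11 in part of the passage 15 cells is a candidate explanation. After the correction, all 8 blocks of about 100 neighbouring genes lay above 0, the lowest at 0.143 ± 0.0289 (SE), and none of the 126 blocks of other autosomes exceeded it. The uncorrected blocks, between 0.124 and 0.266, had been seen when this test was written, and the chromosome was picked as the largest of 22. The correction moved genes by a median of only 0.0713. The test therefore had little room to exclude the explanation and cannot establish it. Genes on a chromosome are not independent replicates, the shift is a factor of 1.15, and no DNA was measured in these libraries.

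Endoderm or mesoderm cells in the passage 15 cultures could have brought GATA4 (5.55 TPM) and HAND1, and the tables leave this open. Of the 24 other endoderm and mesoderm genes under 1 TPM at passage 10, the highest at passage 15 was TBX4 with 0.62 TPM. Among those above 1 TPM, the endoderm factor HNF4A rose when adjusted over the list alone, from 1.77 ± 0.403 to 4.16 ± 0.516 TPM (SD, n = 2; limma adjusted p = 0.104 over all genes), while APOA2, an apolipoprotein gene of liver and yolk sac, had 40.3 ± 21.2 TPM at passage 10 and 16.3 ± 1.90 at passage 15 (adjusted p = 0.127).

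For the 204 genes called between the passages, the 4 libraries allow only 3 splits into equal groups, too few for a share under 0.05. The real split was the only 1 with that many genes, and the highest other split called 1.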
